A study of Homo sapiens with 6 samples.

How the data were processed

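The series has 6 GEO samples: gene expression libraries and cell tag libraries of 2 pools, of which the A375 pool was sequenced in 2 runs. Cells were labelled with CellPlex tags, pooled by line and loaded on the Chromium platform with 3′ chemistry, per the labels' protocols. The deposited tables hold raw UMI counts per gene and cell, per the labels' description, and the values are whole numbers whose totals differ between cells. The submitters' processing notes name Cell Ranger 7.0.0 and the GRCh38 build. Which genes and cells were left out before deposition is not stated, and a gene was detected in at least 9 cells of the A375 table and 6 of the PC9 table. The authors' cell tables list 5059 A375 cells (59.5%) and 4208 PC9 cells (37.4%) with their total count, number of genes, percent of mitochondrial UMIs and cluster, per the file headers. Counts and percents of all listed cells matched the count tables, the percents within 0.001. How the listed cells were chosen is not stated. The deposited names of the cell tables hold g1, which may stand for the G1 phase of the cell cycle. S-phase and G2 and M-phase genes of the listed cells were lower than in all cells. The listed cells were used as an alternative. The population is the suffix of each cell name, and the suffix T05 was matched to the label T0500.

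All cells were used. The highest mitochondrial share of a cell was 59.0% in the A375 table and 20.0% in the PC9 table, and the most genes in a cell 7800 and 4932. No doublet caller was run, and cells with more than 2 times the median UMIs were left out in an alternative. UMIs were summed per population and divided by the population's total to give counts per 1000000 UMIs (CPM). Ratios were taken as log2(CPM + 1), and fold values are ratios of CPM with 95% exact binomial counting intervals. A gene was measured when it had at least 10 CPM and 20 UMIs in the higher population of a comparison, and counted as different at 2-fold or more. With 1 culture per population no test between conditions is possible and no p-value is given. The floor for a gene without UMIs was 3 counts of the total. The A375 runs could not be told apart in the cell names. The tag libraries were used only through the population names.

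The 8 comparisons set the top dose and the lowest dose against untreated cells and against each other in each line, and the PC9 persisters against untreated cells and against the top dose. Named genes were the 10 with the highest and the 10 with the lowest ratio among genes with at least 25 CPM in the higher population, without clone-named, antisense and LINC genes. To these were added the drug target, up to 4 members with the largest ratios of each list outside the middle 95% of random lists, and up to 10 genes per direction shared by the lines. Genes named for their values by dose, EIF5 and TRAF3 in the chromosome 14 segment, markers of other cell types and genes of the closing section outside this rule were chosen after their values were seen. Comparisons, naming rule, gene lists and most alternatives were fixed before the data were examined.

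For each of 37 gene lists the median log2 ratio over measured members was placed among the medians of 10000 random lists of equal size, matched on mean expression in 20 bins. This describes these libraries and is not a test across conditions. Lists of markers of other cells (immune, endothelial, fibroblast, erythroid, and lung epithelial and epithelial genes in A375, melanocyte genes in PC9) were included. Distances between populations are root mean square differences of log2(CPM + 1) over measured genes. Per-cell shares were computed after thinning cells to 4638 UMIs in A375 and 3832 in PC9, for the 50 genes with the highest or lowest ratios at the top dose, chosen in a random part of the cells and scored in the rest. A simulation of unchanged populations, intended for the genes shared by persisters and adapted cells, is not used for them, because no unchanged gene reached 2-fold in simulated data at these depths. Gene positions came from GENCODE v29 by symbol, which placed 99.5% of symbols in each line. Segments of neighbouring genes were scored with a log2 step of 0.75 and set against 100 shuffled gene orders.

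Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with edgeR 4.0.16 for trimmed mean (TMM) factors. The gene ratios, intervals and list percentiles were tested on simulated data for all 8 comparisons. For 4 µM against untreated A375 cells, 50 of 50 genes set 3-fold apart were called, 0 of 50 set 1.5-fold apart, and 0 of 9393 genes without a difference, and 94.6% of ratios lay in their intervals. The simulated counts held counting error alone, so the test cannot show how the intervals hold with spread between cells. In a random part of the real cells 90 of 758 ratios of named genes lay outside the reported interval. Alternatives were a pseudocount of 5 CPM, no CPM filter, a minimum of 50 CPM, a threshold of 3-fold, TMM factors, totals without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, cells of the authors' cell table, trimming of cells by UMIs, a random part of the cells, thinning to the shallowest population, and other sizes of the per-cell gene set. Reads of near-identical gene copies cannot be told apart in counts by symbol, so genes with close paralogs or pseudogenes, such as FTH1 and HSP90AA1, are less certain.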

Results

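Single-cell RNA sequencing counted unique molecular identifiers (UMIs) per gene in 2 human cancer cell lines kept in increasing doses of a targeted inhibitor. A375 is a melanoma line with mutant BRAF and was grown in dabrafenib, an inhibitor of the BRAF kinase. PC9 is a lung adenocarcinoma line with mutant EGFR and was grown in osimertinib, an inhibitor of the EGFR kinase. The 9 A375 populations were untreated cells and cells adapted to 30, 60, 125, 250 and 500 nM and to 1, 2 and 4 µM dabrafenib. The 10 PC9 populations were untreated cells, cells adapted to 8, 16, 32, 75, 150, 300 and 600 nM and to 1.2 µM osimertinib, and drug-tolerant persisters that outlived 9 days of 1.2 µM given without escalation. Each population was 1 culture, its cells were tagged and pooled with the others of its line, and the adapted populations were derived by stepwise dose escalation. There are no replicates, so differences are given by size, and the 95% intervals in parentheses cover counting error only.

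The A375 table held 8505 cells, 15945 genes and 87053189 UMIs, and that of PC9 held 11258 cells, 15429 genes and 77210300 UMIs. Untreated A375 cells numbered 2011 with 21976644 UMIs in total. The A375 populations from 30 nM to 4 µM held, in order of dose, 7012730, 14753107, 2938641, 7933275, 6841277, 9193771, 8765841 and 7637903 UMIs. Untreated PC9 cells numbered 1315 with 10552237 UMIs. The PC9 populations from 8 nM to 1.2 µM held 6457304, 8897621, 7497766, 9164979, 7520436, 7537672, 7275335 and 7398722 UMIs, and the persisters 4908228. Median UMIs per cell lay between 7337 and 9804 in A375 populations and between 5776 and 7968 in PC9 populations. A gene without a UMI in a population can have had up to 1.02 counts per 1000000 UMIs (CPM) in the shallowest A375 population and up to 0.611 CPM in the shallowest PC9 population.

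Cells adapted to 4 µM dabrafenib were set against untreated A375 cells to ask how a melanoma line living at the highest dose differs from its parent. TAGLN, an actin-binding protein of smooth muscle, was 22-fold higher (21.3 to 22.7) at 4066 against 185 CPM, and ACTA2, smooth muscle actin, was 20.9-fold higher (19.6 to 22.4). MYOCD, a coactivator of smooth muscle genes, was 22.1-fold higher (19.1 to 25.8), and the actin nucleator LMOD1 and the calcium channel CACNA1C were 22.8-fold higher (18.5 to 28.5) and 24.8-fold higher (21.1 to 29.2). SOX10, the factor that keeps melanocytic and neural crest identity, was 5.43-fold lower (4.83 to 6.14), and SPRY4, a feedback inhibitor transcribed on ERK signalling, was 12.2-fold lower (9.73 to 15.4). BRAF itself (chromosome 7, 140719327 to 140924928, GRCh38) was 1.19-fold lower (1.10 to 1.29) at 98.6 against 117 CPM. Of 9946 genes measured, 556 were at least 2-fold higher and 884 at least 2-fold lower. The median log2 ratio of all genes was -0.17, and -0.07 with scaling by trimmed means, so ratios near 0 depend on the scaling. When cells with more than 2 times the median UMIs of their population were left out, the log2 ratio of TAGLN was 6.09 in place of 4.45, and that of ACTA2 5.68 in place of 4.36.

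Transcriptional output of the MAPK pathway was lower at 4 µM in 9 of 16 genes and higher in 1, with a median log2 ratio of -1.29. In the 8 comparisons the list medians given lay outside the middle 95% of those of 10000 random lists matched on expression, unless stated otherwise. Among the MAPK genes were the ETS factor ETV4, 7.47-fold lower, and the cell cycle driver CCND1, 4.12-fold lower (3.82 to 4.44) at 98.1 against 404 CPM. Matrix and mesenchymal genes went the other way in 12 of 30 cases, with 3 lower. Fibronectin (FN1) was 8.19-fold higher (7.54 to 8.91), the matrix protein periostin (POSTN) 14.9-fold higher (13.1 to 17.1) and the fibrillar collagen COL3A1 28.2-fold higher. Targets of YAP and TEAD were 2-fold higher in 7 of 20 genes and lower in 1, with the ligand TGFB2 higher at 10.5-fold (8.78 to 12.5) and the matricellular gene CYR61 at 3.25-fold (3.06 to 3.45). Of 10 complement and innate defence genes 7 were higher, with a median log2 ratio of 1.73, and the central complement component C3 was 9.67-fold higher (7.58 to 12.4). The complement median was 0.34 and inside the range of random lists when only genes at 50 CPM or more were kept.

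Melanocytic and neural crest genes split in direction at 4 µM. The pigment enzyme DCT was 4.74-fold higher (3.83 to 5.87), whereas the glial marker S100B was 3.30-fold lower (2.97 to 3.67). In the neural crest list the progenitor filament NES was 10.0-fold lower (8.24 to 12.3) and the factor TFAP2B 3.14-fold lower, but SOX9, which acts in neural crest and cartilage, was 8.41-fold higher (6.31 to 11.3) and SNAI2, an inducer of mesenchymal transition, 3.87-fold higher. The list medians were -0.66 for melanocyte genes and -0.73 for neural crest genes. They were inside the range of random lists with per-cell averaging (-0.54) and with totals that leave out mitochondrial and ribosomal protein genes (-0.40), respectively.

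Proliferation genes were lower at 4 µM across all cells. Of 39 S-phase genes 33 were 2-fold lower and none higher, and of 51 G2 and M-phase genes 41 were 2-fold lower, with medians of -1.61 and -1.41. The replication checkpoint mediator CLSPN was 5.47-fold lower (4.60 to 6.56) and the mitotic ubiquitin-conjugating enzyme UBE2C 3.67-fold lower (3.30 to 4.09). Targets of p53 had a median of 0.51, and the cell cycle inhibitor CDKN1A was 2.14-fold higher (1.92 to 2.39). Interferon response genes had a median of 0.72 with the antiviral membrane protein IFITM3 at 2.32-fold (2.20 to 2.45), and antigen presentation genes 0.59 with B2M, the light chain of MHC class I, 1.87-fold higher. In the cells of the authors' cell table alone, the S-phase median was -0.37 and the G2 and M-phase median -0.21, both inside the range of random lists. In these cells the log2 ratio of CDKN1A was 0.76, no longer 2-fold. It was also under 2-fold in a random part of the cells, at 0.55, and after thinning to the shallowest population, at 0.81.

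Genes that mark other cell types were measured as well. Of 4 fibroblast markers measured 3 were higher at 4 µM, the collagen COL3A1, the surface protease FAP at 14.3-fold (10.1 to 20.7) and the proteoglycan LUM at 6.58-fold (5.40 to 8.04). Of 3 lung epithelial genes measured all 3 were higher, with a median of 2.37, led by the transcription cofactor LMO3 at 32.0-fold (23.1 to 45.4). The 3 epithelial genes measured had a median of 0.85. Of the immune markers only CD68, a lysosomal protein, was measurable, and it was higher with a log2 ratio of 1.27. No endothelial or erythroid marker reached the minimum level. The median share of mitochondrial UMIs per cell was 7.67% at 4 µM and 5.22% in untreated cells, and 10.6% against 0.796% of cells had 20% or more.

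Cells adapted to 30 nM dabrafenib, the lowest dose, were set against untreated A375 cells to ask what the first step of escalation brings. The nerve growth factor receptor NGFR, a marker of neural crest-like melanoma cells, was 13.3-fold higher (11 to 16.2) at 80.4 against 6.05 CPM, and the pigment enzyme DCT was 16.8-fold higher (14 to 20.2). The secreted matricellular protein NOV was 15.1-fold higher (12.5 to 18.3) and the proteoglycan LUM 11.3-fold higher (9.41 to 13.7). The ferritin heavy chain FTH1, which stores iron, was 4.18-fold higher (4.14 to 4.21) at 18709 against 4477 CPM. SPRY4 was 9.01-fold lower (7.36 to 11.1) and ETV4 6.78-fold lower (5.47 to 8.50), while BRAF stood at 109 against 117 CPM. Of 9882 genes 398 were 2-fold higher and 491 lower, or 527 and 489 in the cells of the authors' cell table. Under per-cell averaging the log2 ratio of DCT was 5.03 in place of 3.88 and that of NGFR 4.25 in place of 3.53.

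At 30 nM 10 of 16 MAPK output genes were lower, with a median of -1.17. Of 28 mesenchymal genes 9 were higher and 3 lower. TGF-beta target genes had a median of 0.52, and ID3, an inhibitor of differentiation induced by this pathway, was 3.53-fold higher (3.41 to 3.66) at 889.8 against 252 CPM. The oxidative stress list had a small median of 0.21, with the haem-degrading enzyme HMOX1 3.54-fold higher (2.95 to 4.24) and the quinone reductase NQO1 2.54-fold lower (2.43 to 2.67). The fatty acid synthase FASN was 2.63-fold lower (2.32 to 2.99), and the scavenger receptor CD36, which takes up fatty acids, was 9.10-fold higher (5.99 to 14.2). Of 39 S-phase genes 21 were lower, with a median of -1.07. The 3 fibroblast markers measured were all higher, with a median of 2.91. CD68 had a log2 ratio of 1.67, the only lung epithelial gene measured, SLPI, 1.09, and the 3 epithelial genes a median of 0.68, which was 0.48 and inside the range of random lists in the authors' cell table. In the cells of the authors' cell table the S-phase median was -0.20, and among genes at 50 CPM or more the antioxidant median was 0.01, both inside the range of random lists.

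The comparison of 4 µM with 30 nM asked what differs between the ends of the escalation once cells are adapted. NGFR was 34.1-fold lower (21.4 to 58.0) at 2.36 against 80.4 CPM, and FOXD3, a factor of the premigratory neural crest, was 9.49-fold lower (6.68 to 13.9). SOX10 was 3.60-fold lower (3.15 to 4.11), and the receptor ERBB3, which SOX10 activates in the neural crest lineage, was 3.65-fold lower. The repressor ZEB2, which goes with melanocytic differentiation, was 4.43-fold lower (3.98 to 4.93). TAGLN was 8.84-fold higher (8.52 to 9.17), ACTA2 9.22-fold higher (8.53 to 9.98) and the heparan sulphate proteoglycan GPC5 14.2-fold higher (13.0 to 15.5) at 1122 against 79.1 CPM. Of 8 melanocyte lineage genes 5 were lower and 1 higher, with a median of -1.49. The MAPK output genes had a median of -0.13, inside the range of random lists. Of 9766 genes 285 were higher and 321 lower, and the all-gene median was -0.10, or 0.01 with scaling by trimmed means, which gave 336 higher and 281 lower.

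Values by dose in A375 did not follow a single course. TAGLN stood at 185 CPM in untreated cells, 460.2 at 30 nM, 292 at 60 nM, 166 at 250 nM, 795 at 500 nM and 4066 at 4 µM. SPRY4 was 14 CPM at 30 nM, 95.2 at 60 nM, 94.6 at 125 nM and 11.8 at 500 nM. FTH1 was 18709 CPM at 30 nM, 3411 at 125 nM and 22978 at 1 µM. SOX10 was 211 CPM at 250 nM, close to 208 in untreated cells, and 29.9 at 1 µM. The MAPK output list had a median log2 ratio to untreated cells of -1.17 at 30 nM, 0.09 at 60 nM, 0.02 at 250 nM and -0.94 at 500 nM. At 250 nM its members split, with 6 of 17 at least 2-fold lower and 2 higher. AP-1 factors, which drive stress and growth responses, were highest at 250 nM with a median of 1.58, against 0.35 at 4 µM. S-phase genes were below untreated cells at every dose, with medians from -2.01 at 125 nM to -0.90 at 60 nM.

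Distances between populations, as root mean square log2 differences over genes, placed 30 nM nearer to 500 nM (0.38) than to 60 nM (0.50). The 60 nM population lay 0.41 from untreated cells and the 4 µM population 0.80. Between 250 and 500 nM the distance was 0.64, and between 1 and 2 µM it was 0.19. From 500 nM to 1 µM 14 genes were 2-fold higher and 110 lower, and from 1 to 2 µM 8 and 3. The step from 250 to 500 nM held 446 genes in each direction. On its lower side FTH1 stood at 4092 CPM and on its upper side at 21113 CPM, and SOX10 at 211 and 68.0 CPM.

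**Figure D1:**
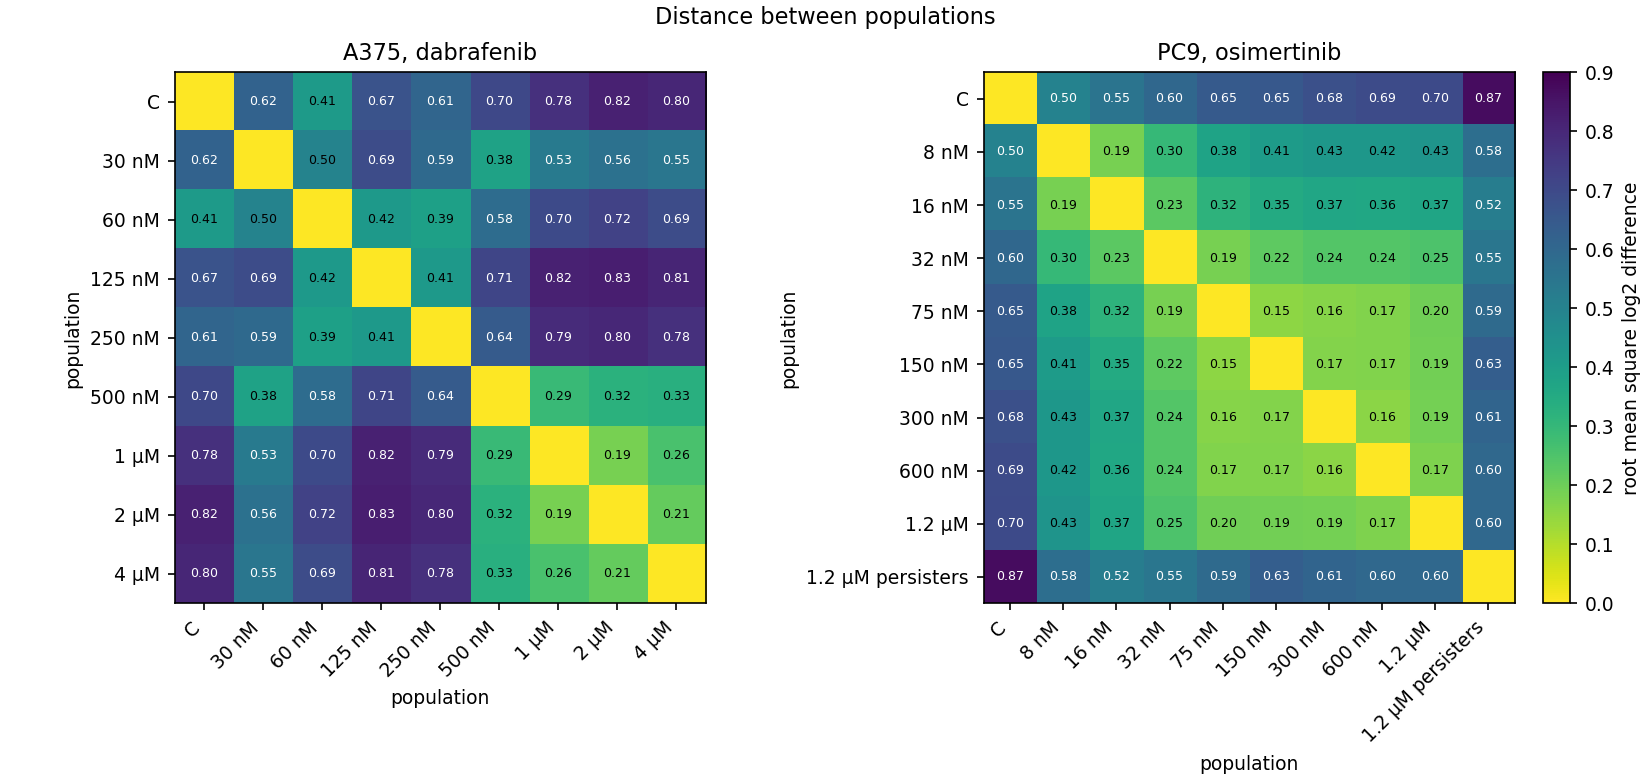
Root mean square log2(CPM + 1) distance between each pair of populations, by line, on a colour scale. A375 at 30 nM is 0.38 from 500 nM and 0.50 from 60 nM, and PC9 persisters are 0.52 from 16 nM and 0.60 from 1.2 µM.

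Cells adapted to 1.2 µM osimertinib were set against untreated PC9 cells to ask how a lung cancer line living at the highest dose differs from its parent. NUPR1, a stress-induced chromatin protein, was 42.6-fold higher (29.9 to 62.6) at 129 against 3.03 CPM, and NNMT, which consumes methyl groups, was 44.5-fold higher (25.1 to 86.8). GFRA1, a co-receptor of RET, was 140.5-fold higher (38.4 to 1168), with 2 UMIs in untreated cells. The antiviral GTPase MX1 was 19.8-fold higher (13.8 to 29.5). On the lower side were the adhesion molecule CEACAM6, 46.3-fold lower (29.6 to 77.2), the chromatin protein HMGA2, 15.6-fold lower (13.2 to 18.5), and the mesenchymal filament VIM, 20.8-fold lower (13.2 to 34.8) at 2.57 against 53.4 CPM. The mesenchymal list went the other way, with 9 of 21 genes higher, 3 lower and a median of 0.85. The drug target EGFR (chromosome 7, 55019021 to 55211628, GRCh38) was 1.82-fold lower (1.76 to 1.89) at 539 against 981 CPM. Of 9477 genes 569 were 2-fold higher and 366 lower, or 504 and 446 with scaling by trimmed means. In the cells of the authors' cell table the log2 ratio of MX1 was 6.38 in place of 3.91.

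Interferon response genes were the list with the highest median in PC9 at 1.2 µM, 1.90, and 25 of 31 were 2-fold higher. The oligoadenylate synthetase OAS2 was 28.0-fold higher (11.6 to 88.0) and HLA-B, which presents peptides to T cells, 3.28-fold higher (2.92 to 3.69). Of 22 YAP and TEAD targets 12 were higher and 1 lower, with TGFB2 at 6.27-fold (5.71 to 6.89). TAGLN was 10.5-fold higher (9.10 to 12.1) and the tropomyosin TPM1 5.67-fold higher. Cholesterol synthesis genes had a median of 0.98, and SREBF2, the factor that controls them, was 2.73-fold higher (2.38 to 3.14). Among receptor kinases and ligands the receptor FGFR1 was 3.49-fold higher (2.82 to 4.34) and the EGFR ligand AREG 8.99-fold lower (6.07 to 13.8).

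MAPK output genes had a median of -0.53 in PC9 at 1.2 µM, with 6 of 15 lower and 1 higher. The ERK phosphatase DUSP6 was 16.5-fold lower (8.19 to 38.7), while the immediate early factor EGR1 was 9.27-fold higher (6.37 to 13.9). S-phase genes had a median of -0.48 with 1 of 38 lower by 2-fold, and G2 and M-phase genes -0.01, the latter inside the range of random lists. The antimicrobial lipocalin LCN2 was 3.41-fold lower (3.24 to 3.58) and C3 6.47-fold lower (4.58 to 9.39), while the complement inhibitor SERPING1 was 9.65-fold higher. The complement list median of 0.43 was 0.04 in the cells of the cell table, inside the range of random lists. Of the markers of other cells, CD68 had a log2 ratio of -1.08, the endothelial gene ESAM -1.05 and the collagen COL1A1 1.08, and no erythroid marker reached the minimum level. The 5 melanocyte lineage genes measured had a median of 0.23, inside that range.

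The chaperone HSP90AA1 (chromosome 14, 102080738 to 102139699) was 6.56-fold lower (6.43 to 6.70) at 1.2 µM, at 1381 against 9061 CPM. Its neighbours from PPP2R5C to ZFYVE21 (101761798 to 103733668) were examined after this value was seen. Of the other 20 genes in this segment 18 were 2-fold lower, with a median log2 ratio of -1.71, against -0.15 for 20 flanking genes. The segment's ends were fitted to these same ratios by the scan of neighbouring genes. Its low median and the contrast with the flanks follow partly from that choice. The scan score was 18.6, against at most 7.79 in 100 shuffled gene orders. The segment's median was -0.24 at 16 nM, -0.96 at 32 nM and -1.57 at 75 nM, and -0.38 in persisters, where HSP90AA1 itself had a log2 ratio of -1.10. The translation factor EIF5 and the signalling adaptor TRAF3, both in the segment, had log2 ratios of -1.59 and -1.45 at 1.2 µM. The median share of a cell's UMIs in the segment's 20 genes other than HSP90AA1 was 0.287% in untreated cells and 0.0886% at 1.2 µM.

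**Figure D2:**
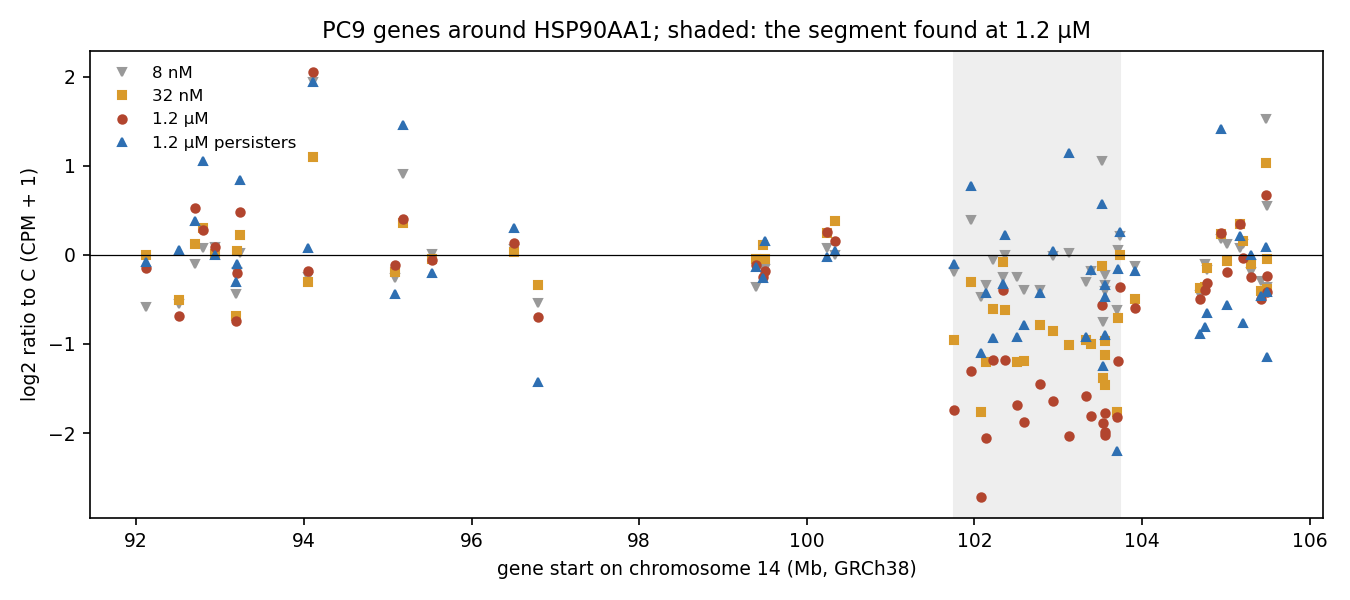
Log2 ratio to untreated PC9 cells of genes along chromosome 14 (position in Mb, GRCh38) by population. The segment's 20 genes other than HSP90AA1 have a median of -1.71 at 1.2 µM and -0.38 in persisters, and the flanking genes -0.15 at 1.2 µM. The segment's ends were fitted to the ratios at 1.2 µM.

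Cells adapted to 8 nM osimertinib were set against untreated PC9 cells to ask what the lowest dose brings. IGFBP5, which binds insulin-like growth factors, was 13.9-fold higher (11 to 17.6) at 109 against 7.87 CPM, and TAGLN was 7.41-fold higher (6.41 to 8.58). Fibronectin was 4.80-fold higher and TGFB2 4.12-fold higher. HMGA2 was 17.1-fold lower (14.2 to 20.7) at 18.1 against 309 CPM, VIM 5.23-fold lower (4.05 to 6.86) and DUSP6 12.8-fold lower (6.59 to 28.4). MX1 was 5.85-fold higher (3.9 to 9.02) and HLA-B 3.37-fold higher (3.0 to 3.8). EGFR was 1.27-fold lower (1.23 to 1.31). Of 9338 genes 294 were higher and 165 lower, and the interferon, YAP and TEAD and cholesterol lists had medians of 0.88, 0.77 and 0.68. Of 18 mesenchymal genes 7 were higher and 4 lower, with a median of 0.53. AP-1 factors had a median of 0.48, and 0.08 in the cells of the cell table, inside the range of random lists. There the log2 ratio of IGFBP5 was 2.18 in place of 3.64.

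The comparison of 1.2 µM with 8 nM asked what differs between the ends of the escalation in PC9. NNMT was 54.4-fold higher (24.8 to 149), NUPR1 12.3-fold higher (9.58 to 15.9) and KISS1, a secreted peptide that suppresses metastasis, 7.88-fold higher (6.96 to 8.94) at 344 against 43.7 CPM. FGFR1 was 6.74-fold higher (4.81 to 9.66) and the bone morphogenetic protein BMP6 20.7-fold higher. HSP90AA1 was 4.72-fold lower (4.62 to 4.83) and KRT13, a keratin of stratified epithelium, 6.20-fold lower (5.58 to 6.90). Interferon response genes were higher in 13 of 30 cases with a median of 0.89, whereas MAPK output genes had a median of 0.06, inside the range of random lists. EGFR was 1.44-fold lower (1.38 to 1.5). Of 9401 genes 153 were higher and 128 lower.

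The 4 largest steps between consecutive PC9 populations lay at or below 75 nM. NUPR1 stood at 3.03 CPM in untreated cells, 10.5 at 8 nM, 40.9 at 32 nM, 80.5 at 75 nM and 129 at 1.2 µM. KISS1 was 61.3 CPM at 16 nM and 176 at 32 nM, and FGFR1 6.04 at 8 nM and 34.8 at 32 nM. MX1 was 17.2 CPM at 8 nM, 32.6 at 600 nM and 58.3 at 1.2 µM. LCN2 was lower along the doses, with 735 CPM at 8 nM and 322 at 75 nM. Consecutive populations from 75 nM on lay 0.15 to 0.17 apart, and the first step, from untreated to 8 nM, measured 0.50.

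**Figure D3:**
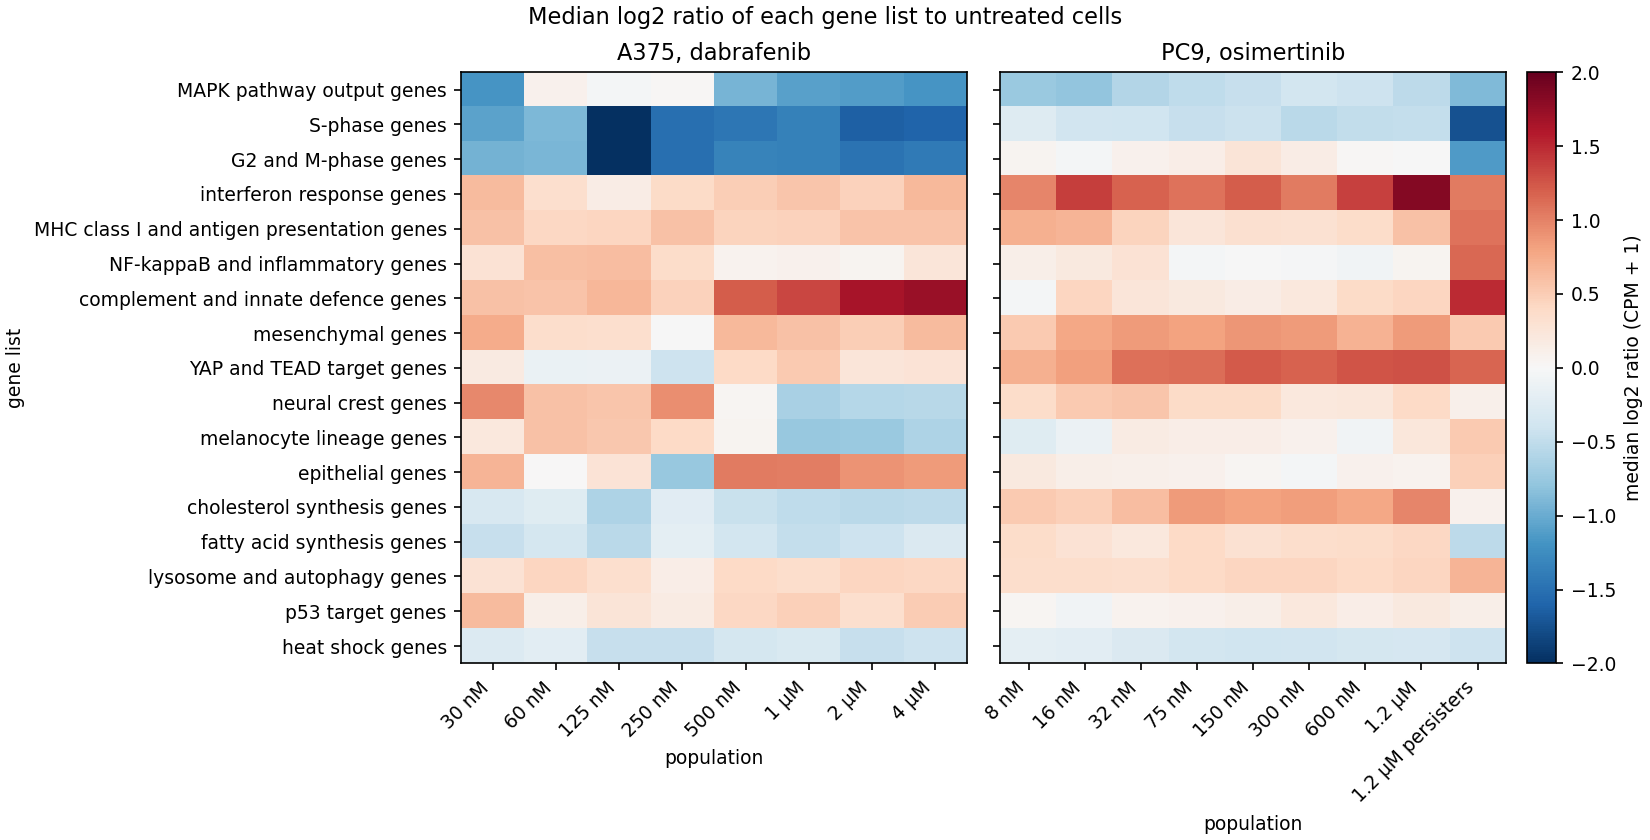
Median log2 ratio to untreated cells of gene lists (vertical axis) by population in order of dose, with A375 and PC9 in separate panels. Each list has the same members at every dose. The MAPK output list in A375, with 17 members, stands at -1.17 at 30 nM, 0.09 at 60 nM and -1.19 at 4 µM.

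Persisters were set against untreated PC9 cells to ask what acute exposure to the top dose leaves in the surviving cells. The membrane protein PDZK1IP1 was 28.3-fold higher (24.3 to 33.1) and IGFBP5 27.4-fold higher (21.9 to 34.6). The adhesion molecule ICAM1, induced by NF-kappaB, was 11.4-fold higher (8.72 to 15.2), the complement protease C1S 10.7-fold higher (8.83 to 13.0) and HLA-B 6.72-fold higher (6.01 to 7.51) at 267 against 39.8 CPM. HMGA2 was 32.3-fold lower (24.2 to 44.1), the laminin receptor ITGA6 9.94-fold lower (8.93 to 11.1) and CLSPN 6.49-fold lower (5.42 to 7.84). EGFR was 1.31-fold lower (1.26 to 1.36). Of 9646 genes 1027 were higher and 929 lower, or 958 and 1034 with scaling by trimmed means. In the cells of the authors' cell table the log2 ratio of IGFBP5 was 3.11 in place of 4.61 and that of ICAM1 4.46 in place of 3.31.

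Proliferation genes were lower in persisters in 37 of 38 S-phase and 34 of 50 G2 and M-phase genes, with medians of -1.73 and -1.13. Complement and innate defence genes had a median of 1.5, NF-kappaB and inflammatory genes 1.14 and antigen presentation genes 1.09. LCN2 stood at 4379 against 878 CPM. Of 15 MAPK output genes 7 were lower and 2 higher, with a median of -0.88. AP-1 factors had a median of 1.18, and FOS, their immediate early member, was 4.88-fold higher (4.24 to 5.64). Of 26 lysosome and autophagy genes 9 were higher, among them the autophagosome protein GABARAPL1 at 6.85-fold (5.87 to 8.03). Glycolysis genes had a median of -0.63, with the hexokinase HK2 4.58-fold lower (2.92 to 7.57) and the enolase ENO1 2.54-fold lower (2.41 to 2.67). The mucin MUC1 was 7.70-fold higher (6.0 to 9.97). CDKN2B, an inhibitor of G1 cyclin kinases, was 9.59-fold higher (7.31 to 12.8).

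The comparison of persisters with cells adapted to the same 1.2 µM asked how acute survival differs from growth at that dose. LCN2 was 17.0-fold higher (16.2 to 17.8) at 4379 against 258 CPM and C3 20.4-fold higher (14.5 to 29.5). The neutrophil chemokine CXCL8 was 12.7-fold higher (6.36 to 28.9), and TNFAIP2, an inflammatory gene in the chromosome 14 segment, 9.76-fold higher (7.79 to 12.3). KISS1 was 16.9-fold lower (13.8 to 20.8), NNMT 14.6-fold lower (8.99 to 25.3), the desaturase SCD, which makes monounsaturated fatty acids, 8.47-fold lower (5.43 to 13.9), and MX1 4.85-fold lower (3.69 to 6.47). Cholesterol synthesis genes had a median of -0.74 and fatty acid synthesis genes -0.74. Interferon response genes were lower in 11 of 31 cases and NF-kappaB genes higher in 8 of 13. The BCL2 family had a median of 0.37, inside the range of random lists at 50 CPM or more, and its cell death activator BMF was 8.89-fold higher (4.51 to 19.5). EGFR was 1.39-fold higher (1.33 to 1.45). Of 9544 genes 385 were higher and 407 lower, or 405 and 385 with scaling by trimmed means. The replication enzyme TYMS was 3.49-fold lower (3.0 to 4.08), but its log2 ratio was -0.86 in the cells of the authors' cell table, no longer 2-fold. Summed S-phase genes stood at 998 against 2389 CPM in all cells and at 530 against 877 CPM in the cell table. For G2 and M-phase genes these levels were 2597 against 5758 CPM and 1037 against 1665 CPM.

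Persisters and cells adapted to 1.2 µM shared 397 genes that were 2-fold higher and 215 that were 2-fold lower than untreated cells, where 44.8 and 36.5 would overlap if the sets were independent. In 8 genes the directions were opposite. HLA-B stood at 39.8 CPM in untreated cells, 131 CPM in adapted cells and 267 CPM in persisters, and HMGA2 at 309, 19.9 and 9.58 CPM. Both ratios share the untreated culture, which can raise the overlap by an amount not measured here. Across 9312 genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.756 and Spearman's rho 0.739. Their covariance was 0.426, against 0.00635 in a simulation of counting error alone with a shared control. Pearson's r in that simulation, 0.385, is no baseline for 0.756, because all variance there is counting error. Persisters were nearest to the 16 nM population at a distance of 0.52.

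The lines were compared at their top doses to ask which responses to BRAF and EGFR inhibition they have in common. TAGLN and the myosin light chain MYL9 were higher in both, MYL9 by 13.7-fold in A375 and 7.12-fold in PC9. The synaptic adhesion molecule TENM2 was higher by 12.1-fold and 28.2-fold, NUPR1 by 10.1-fold and 42.6-fold, and the sodium channel SCN9A by 14-fold and 12.8-fold. ETV4 was lower in both, by 7.47-fold and 4.44-fold, as were ITGA6 by 4.94-fold and 5.62-fold and the chloride channel ANO1 by 10.9-fold and 7.61-fold. Of 8490 genes measured in both lines 88 were higher in both and 53 lower in both, where 14.8 and 18.6 would be by independence. In A375 higher and PC9 lower were 23 genes, and the reverse held for 29, where 9.30 and 29.5 would be. Across genes, which are not independent replicates, Pearson's r was 0.32 and Spearman's rho 0.30.

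Per-cell values asked whether the differences were spread over the cells of a population. The 50 genes with the highest ratios at the top dose, chosen in a random part of the cells and scored in the rest at equal depth, took a median of 1.51% of UMIs at 4 µM in A375 and 0.0216% in untreated cells. Beyond the 95th percentile of untreated cells were 93.2% (89.9 to 95.8) of cells at 4 µM, 22.4% (17.7 to 27.8) at 30 nM, 8.72% (6.18 to 11.9) at 250 nM and 63.3% (57.5 to 68.8) at 500 nM. This limit, 0.385% of UMIs, was set by the highest untreated cells, while the upper quartile of untreated cells was 0.0431%. At 30 nM the median was 0.151% and the quartiles 0.0862% and 0.367%, so the share beyond the limit leaves out a smaller shift in most cells. In PC9 these shares were 69.1% (64.5 to 73.4) at 8 nM, 97.0% (95.3 to 98.2) at 75 nM, 99.2% (97.9 to 99.8) at 1.2 µM and 92.9% (89.5 to 95.4) in persisters. They depended on the number of genes, with 36.1% for 20 genes and 85.8% for 100 genes at 8 nM. Genes lower at 4 µM were below the matching limit in 69.0% of A375 cells at 30 nM and in 19.9% at 60 nM.

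**Figure D4:**
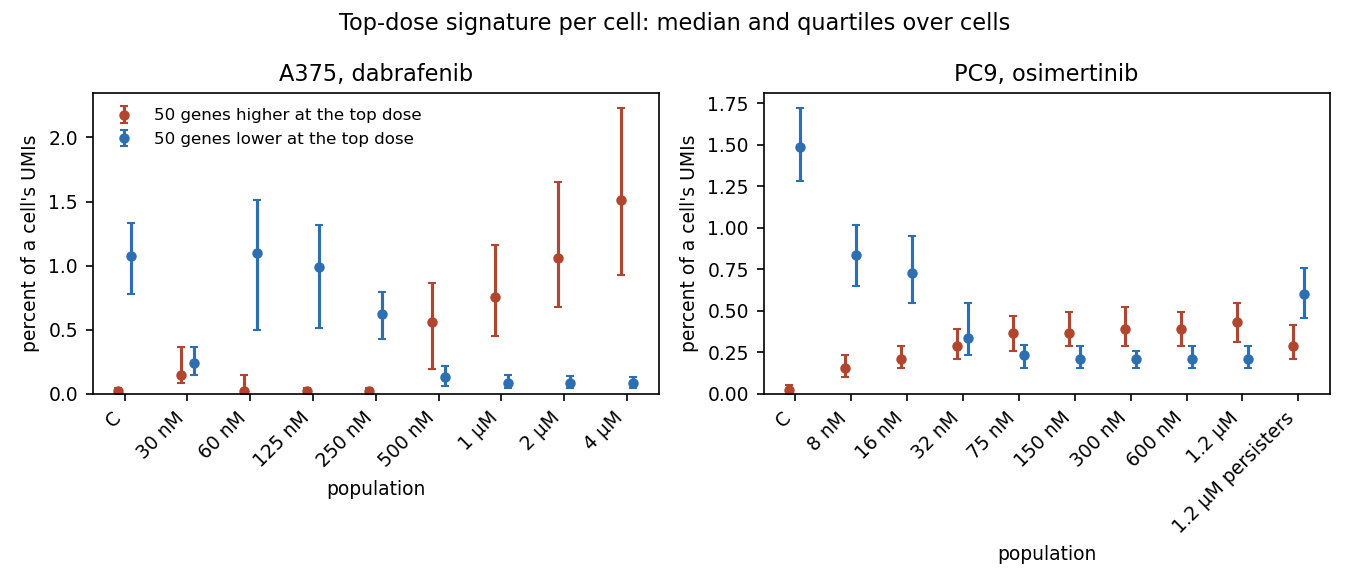
Share of each cell's UMIs (percent) in the 50 genes highest at the top dose, as median and quartiles per population in order of dose, with A375 and PC9 in separate panels. The A375 median is 0.0216% in untreated cells and 1.51% at 4 µM, and the PC9 median 0.0261% and 0.431%.

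Cell cycle content differed between populations and between the sets of cells deposited. In untreated A375 cells the G2 and M-phase genes summed to 1184 CPM in the cell table and 6870 CPM in the cells outside it. A choice of listed cells by phase would itself bring populations together in these genes. Levels within the cell table therefore do not tell how many cells of a population were cycling. The summed level of S-phase genes in A375 was 2629 CPM in untreated cells and 892 CPM at 4 µM, and 762 and 493 CPM in the cells of the authors' cell table. In PC9 it was 3126 CPM in untreated cells, 2389 CPM at 1.2 µM and 998 CPM in persisters, and 1437, 877 and 530 CPM in the cells of the cell table. The cell table held 22% of untreated A375 cells and 64.5% of those at 4 µM, and 12.9% of untreated PC9 cells, 36.8% of those at 1.2 µM and 81.8% of persisters. By the authors' clusters, 77.6% of the listed untreated A375 cells were in cluster 0, and 78.0% of those at 30 nM in cluster 3. At 60 nM 45.1% were in cluster 1 and 28.7% in cluster 3. At 4 µM 36.3% were in cluster 6 and 36.5% in cluster 7. In PC9 85.8% of untreated cells were in cluster 0, 91.2% at 8 nM in cluster 2, 57.2% at 1.2 µM in cluster 4 and 89.0% of persisters in cluster 1.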

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

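The check of these lists under other scalings was chosen only after the result was seen. Measured members were present in either line for 36 gene lists, and any list with too few members in a line was left out. Of the lists compared, 4 had a median log2 ratio to untreated cells of opposite sign in A375 and PC9 at all 8 doses of each line. Cholesterol synthesis genes had a median over the doses of -0.48 in A375 and 0.79 in PC9, with ranges of -0.62 to -0.22 and 0.48 to 0.97. SREBF2, the factor that controls them, stood at 54.1 CPM in untreated A375 cells and 34.6 at 4 µM, and at 30.4 CPM in untreated PC9 cells and 83.1 at 1.2 µM. Fatty acid synthesis genes had medians of -0.38 and 0.36, and the desaturase SCD stood at 71.7 CPM in untreated A375 cells and 63.9 at 4 µM, against 10.1 and 36.2 CPM in PC9. Translation and ribosome protein genes had medians of 0.25 and -0.14, and chromatin regulators -0.22 and 0.073. Not all of these medians lay outside the middle 95% of random lists. Fatty acid synthesis genes were at percentile 24.5 at 4 µM in A375. In PC9 translation genes were at 3.4 and 9.2 and chromatin regulators at 71.2 and 56.6, at 1.2 µM and 8 nM. In A375 chromatin regulators were at 10.9 at 30 nM.

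The difference between the lines was not tested, since each line has 1 culture per dose and the doses were derived stepwise, so that 8 doses are not 8 independent values. The lines also differ in drug, tissue and pool, which cannot be separated here. The first 3 lists kept their sign at all 8 doses of both lines under TMM factors, totals without mitochondrial and ribosomal protein genes, per-cell averaging and cells of the authors' cell table. The chromatin regulators kept it in A375, but in PC9 they were above 0 at 3 of 8 doses with TMM factors and at 5 of 8 in the cell table. No explanation was tested for these lists.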

How the results depend on the processing

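Chosen only after the data were seen were the alternatives that kept cells with under 20% mitochondrial UMIs, kept cells with at most 2 times the median UMIs, or left out the genes of the chromosome 14 segment. No paired analysis was possible because the run numbers 1 and 2 shared by the A375 gene expression and tag groups number sequencing runs of 1 pool. Taking each A375 run alone was intended but not run, because the cell names do not tell the runs apart. With 1 culture per population, all limits below concern processing and depth, and none the spread between cultures.

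Of 208 counts of genes under alternatives, 159 were within 1.5 times the reported count and 49 were not. All were within it under TMM factors, totals without mitochondrial and ribosomal protein genes, trimming by UMIs, a random part of the cells, thinning and the 3 alternatives added later. With no CPM filter, which admits genes by 20 UMIs alone, the higher genes numbered 835 at 4 µM and 614 at 30 nM against untreated A375 cells and 885 at 1.2 µM against untreated PC9 cells. Higher and lower genes were then 457 and 270 at 8 nM against untreated cells, and 263 and 195 at 1.2 µM against 8 nM. A minimum of 50 CPM, which leaves fewer genes, gave 234 higher and 448 lower at 4 µM, 171 and 236 at 30 nM, and 121 and 149 at 4 µM against 30 nM. In PC9 it gave 235 and 172 at 1.2 µM, 104 and 66 at 8 nM, 48 and 55 at 1.2 µM against 8 nM, 446 and 445 in persisters against untreated cells, and 171 and 154 against 1.2 µM. A 3-fold threshold, stricter by construction, gave 304 and 321, 169 and 141, and 130 and 142 in the A375 comparisons in this order. In PC9 it gave 244 and 136, 90 and 52, 50 and 42, 449 and 251, and 124 and 70. At 3-fold the lines shared 36 higher and 15 lower genes, with 5 and 8 of opposite direction, and persisters and adapted cells shared 154 and 72, with 3 opposite. A pseudocount of 5 CPM, which brings ratios of low genes nearer to 0, gave 193 higher at 8 nM, 93 and 85 at 1.2 µM against 8 nM, and 262 lower in persisters against 1.2 µM.

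Which direction held more genes turned under at least 1 setting in 5 of 8 comparisons, those of 4 µM with 30 nM, 1.2 µM with 8 nM, 30 nM with untreated cells, and persisters with untreated and with adapted cells. Per-cell averaging gave 435 higher genes at 4 µM against 30 nM. Cells of the authors' cell table gave 504 lower there, of which 309 were among those reported. In PC9 they gave 267 lower at 8 nM (113 shared), 262 higher and 230 lower at 1.2 µM against 8 nM (124 and 102 shared), and 258 lower in persisters against 1.2 µM (155 shared), and the cause was not tested. The log2 ratios of named genes gave 7152 values under settings that can move a ratio, which leaves out filters on genes. Of these, 1315 lay outside the reported counting interval and 2 more reversed sign. Among the 1315 were 365 of 758 in the cell table and 228 of 758 with a pseudocount of 5 CPM. Of 550 ratios that were 2-fold, each of a gene in 1 comparison, 464 stayed 2-fold under all settings run, and 5020 of 5174 values did under the settings that can move a ratio. In the cells of the cell table the log2 ratios of 2 cell cycle genes reversed, CDCA8 at 4 µM to 0.58 and CDC25C at 30 nM to 0.45, and the cause was not tested. These cells were low in such genes, with G2 and M-phase sums of 1184 CPM in untreated cells, 1059 at 30 nM and 932 at 4 µM.

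Counts of lists outside the middle 95% of random lists were within 1.5 times in 62 of 64 cases. The exceptions were at 50 CPM or more, 12 for 4 µM against 30 nM and 4 for 1.2 µM against 8 nM. Of 147 such list results, 88 stayed outside under all settings run, on either side. The neural crest list at 30 nM against untreated cells is counted among them, though its sign reversed at 50 CPM or more. Of 2091 list medians 1952 were within 0.25 of the reported value and 8 reversed, and the cause was not tested. At 4 µM against untreated cells the NF-kappaB list was 0.15 with no CPM filter, 0.41 with totals without mitochondrial and ribosomal protein genes and 0.51 in the cell table, and the nuclear OXPHOS list -0.017 with per-cell averaging. At 30 nM the nuclear OXPHOS list was -0.026 in the cell table, and at 50 CPM or more the neural crest list was -0.85 and the complement list -0.16. In persisters against 1.2 µM the MAPK output list was 0.11 at 50 CPM or more.

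Of 57 distances between populations 56 were within 1.5 times the reported value. At 50 CPM or more that from 300 to 600 nM in PC9 was 0.102 in place of 0.157. Of 102 shares of cells 49 lay outside the reported intervals. With 100 genes in place of 50, 32.0% of A375 cells at 30 nM lay beyond the untreated limit. In PC9 20 and 100 genes gave 36.1% and 85.8% at 8 nM, 96.9% and 100% at 1.2 µM, and 69.7% and 99.1% in persisters, and the cause was not tested. The share of called genes that were higher at 4 µM was 38.6%, and 46.0% with TMM factors. Depth limits genes of a few CPM most at 125 nM in A375 and in persisters.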

Other observations

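Chosen only after the result was seen were the tests of doublets and of treated cells with a wrong tag, all 3 tests on HSP90AA1, and the scan of neighbouring genes. The other tests were written down before their results were seen.

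Beyond the comparisons above, A375 at 250 nM had the MHC class II genes from HLA-DRA to HLA-DPB1 (chromosome 6, 32439842 to 33087201) higher, with a median log2 ratio to untreated cells of 1.36 over 16 genes of the region. Its scan score was 7.97, against at most 5.06 in shuffled gene orders. This run and those below were the best-scoring of their populations, chosen on these same ratios. Persisters had a run of 20 genes on chromosome 12 (6988259 to 10329600) higher, from the complement protease C1S to the lectin-like receptor KLRD1. Its median was 1.33 and its score 16.5, against at most 10.8. Part of this run was also higher in adapted cells. At 16 nM the best run held 4 genes, from OLR1 to KLRD1, with a median of 2.36 and a score of 6.63, against at most 6.03. At 8 nM it held 3 genes, from OLR1 to GABARAPL1, with a median of 2.46 and a score not above the shuffled orders. At 1.2 µM in PC9 23 genes on chromosome 19 (53866223 to 55157773), from MYADM to TNNI3, had a median of 1.05. Their score of 10.6 was barely above the highest shuffled score, 10.1. At 32, 75, 150, 300 and 600 nM the run there held only 7 or 8 genes and ended at TFPT. Its medians lay between 1.84 at 150 nM and 2.48 at 300 nM. These scores were also above the shuffled orders, from 7.15 against at most 6.80 at 32 nM to 9.72 against at most 7.65 at 300 nM. A rise across all 23 genes is therefore uncertain. At 4 µM in A375 18 genes on chromosome 18 (5392381 to 11885685), from EPB41L3 to CHMP1B, had a median of 0.69 and a score of 13.2, against at most 9.24. At 1 and 2 µM the run there held only 5 genes, from EPB41L3 to PTPRM, with medians of 2.89 and 3.16. A rise across all 18 genes is therefore uncertain.

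The genes highest at 4 µM were also found in single untreated A375 cells. Of 930 untreated cells scored, 53 (5.70%, 4.30 to 7.39) had at least 0.285% of their UMIs in these genes, the 5th percentile of cells at 4 µM. Of 465 cells below the median UMIs 2 were among them, and of 465 from the median on 51, a ratio of 0.0392. This argues against a resistant-like subset spread evenly over cells of few and many UMIs. A subset of cells with many UMIs would give the same ratio, so it stays open. Cells of 4 µM that carry the untreated tag are argued against as the whole cause by the share of UMIs in genes lower at 4 µM. It stood at 0.390 of the way from cells at 4 µM (0.0830%) to other untreated cells (1.08%), with a bootstrap interval over cells of 0.312 to 0.495. Wrongly tagged cells of other doses, or a mix of such cells with doublets, were not tested. Doublets of an untreated and a treated cell may account for them, since these cells held 2.08 times the median UMIs of the other untreated cells (20309 against 9763). The interval above lies just under the midpoint, where doublets of equal parts with cells of 4 µM would lie, so this stays open. Such cells also set the untreated limit for the shares of cells in A375.

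A375 cells at 60 to 250 nM lay apart from those at 30 nM and at 500 nM and above. A mixture of untreated cells and cells of 30 nM at 60 nM is argued against as the whole cause by 60 genes at least 2-fold outside the range of both, such as the synaptic scaffold DLGAP1 (385 CPM against 76.5 and 33.1) and the nuclear receptor NR4A1 (164 CPM against 48.3 and 37.6). A part of cells like those of 30 nM stays open, since 28.7% of listed cells at 60 nM shared the cluster of 78.0% of those at 30 nM. Cell cycle composition as the whole cause is argued against by the cells of the cell table, in which the distance from 30 to 500 nM was 0.869 of that from 30 to 60 nM (0.845 to 0.912 over random subsets of cells), below the 1 that this cause needs. In all cells the ratio was 0.763, and the subsets reach past the 0.9 set beforehand, so the restriction weakened the pattern and a part from the cell cycle stays open. An exchange of the 30 and 250 nM labels changed the length of the path through the doses by -3.21%, too little to decide, so a wrong label cannot be told apart from the labelled order by this test. A difference in the biology of these populations, which the dose steps name, stays open and untested, as each is 1 culture.

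HSP90AA1 was lower in adapted PC9 cells together with its neighbours on chromosome 14. A lower heat shock response is argued against as the whole cause by the other 12 heat shock genes, of which 0 were 2-fold lower at 1.2 µM and whose median log2 ratio was -0.33, against -2.71 for HSP90AA1. A smaller decrease of these genes stays open. The list of 13 with HSP90AA1 lay at percentile 1.39 of random lists, but inside the middle 95% with per-cell averaging (percentile 2.53) and in the cell table (4.75). Reads shared with pseudogenes or paralogs of HSP90AA1 are argued against as the whole cause by the segment's other 20 genes. Their median was -1.71, but the segment's ends were chosen for low ratios. The scan score, with HSP90AA1 included, was 18.6, against at most 7.79 in 100 shuffled orders scanned alike. A lower copy number of the segment in adapted cells could give such a run. The lowest median of 20 neighbouring genes in shuffled orders was -0.55, but for runs of fixed length not fitted to the ratios. Whether the segment accounts for the whole decrease of HSP90AA1 stays open. At 1.2 µM its log2 ratio lay below the lowest of the segment's other genes (-2.06), and in persisters it was -1.10 where these had a median of -0.38 and a range of -2.20 to 1.15. DNA was not measured, so a lower copy number remains a hypothesis, and a regional change in chromatin was not tested.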
